A study of Caenorhabditis elegans with 2 samples.

How the data were processed

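The samples are 2 biological replicates, per the labels, of whole young adult worms of strain OP720, synchronised by hatching into starvation and collected at 69 h, that express LSL-1 tagged with GFP. Chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. Regions were called by the submitters on each replicate and on both pooled, against a control library, on genome assembly ce11 (WBcel235), per the notes deposited with each sample. The caller, the aligner, the IDR threshold and the read depth are not given in the sources used here, and the control library is not analysed here.

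The score of each region is the deposited signal value on the caller's own scale, so it was used only to rank regions within a list. The deposited −log10 q-value of each region was read for its range and entered no test. The deposited summit offset gives the base of the region with the strongest signal, and all positions refer to it. All 3897 IDR peaks are in the pooled list unchanged, and they are exactly its 3897 regions of highest score, so the 26103 others served as lower-ranked background. IDR peaks had a median width of 436 bp (109 to 1246), and 73 repeat the interval of a peak earlier in the list. No region reached past the end of a reference chromosome.

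Genes came from the Ensembl annotation of WBcel235 and sequence from the RefSeq assembly of the same build. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5' end, and a gene was called bound if the window held an IDR summit. In worms many transcripts are trans-spliced, so the annotated 5' end can lie downstream of the true start. The mitochondrial genome was left out. Before the data were examined, 22 gene lists were fixed by symbol; 3 names had no match and were left out. There are 97 symbols that name more than 1 protein-coding gene, and lsl-1 and unc-119 were kept out of the lists because the transgene carries them. The genes named are lsl-1 and unc-119, the closest genes of the 10 strongest peaks, up to 4 bound members per list with the highest score, and the genes nearest the 5 strongest peaks outside promoter windows. Other genes named only as sharing a peak follow from these. In the closing section rpl-25.1 and asb-2 are named only as examples of unbound list genes on X.

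Shares were compared by two-sided Fisher's exact test, promoter bases by the exact binomial test, and ranks by a permutation test with 100000 resamples. Benjamini-Hochberg adjustment ran over the 22 lists and over the 9 biotypes with at least 50 genes, with a threshold of 0.05. Sequence words within 50 bp of the summit were compared with flanks 200 to 250 bp away by the exact McNemar test, with words chosen on chromosomes I, III and V and tested on II, IV and X. There is 1 group, so no test between groups was possible. Alternatives were a stricter peak set, each replicate's own top list, region midpoints, narrower and wider windows, the closest gene alone, genes with a pooled region, autosomes alone, other match distances and word settings. Further alternatives, chosen after seeing the data, left out tRNA peaks, merged summits closer than 500 bp, left out operon-like genes and kept only noncoding genes outside promoter windows. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

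The scripts were tested on simulated data. Each of the 54 meiosis genes was given a peak with a probability of 60%, and 55.6% of them were called bound. Of all promoters given a simulated peak 100% were called bound, so the difference from 60% was not a loss in recovery. In that simulation 1 list outside the germline lists, stress and heat shock, was also called higher. With 1500 randomly placed peaks alone, 0 lists were called higher. A planted word ranked first, and 0 of 5 words passed with nothing planted. Random peaks were placed without regard to promoters or GC content, so these runs do not measure false calls at real summits.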

Results

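Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult Caenorhabditis elegans, 69 h old and of mixed sex, that carried a transgene encoding the protein LSL-1 fused to green fluorescent protein (GFP). An antibody against GFP recovered the DNA bound by the fusion protein. There were 2 biological replicates in 1 group, so the only comparison of samples is between these replicates, and all others are between classes of genes or regions within 1 list. The deposited lists hold 30000 regions for replicate 1, 26018 for replicate 2 and 30000 for both pooled, background regions included. A further list holds the 3897 peaks kept after thresholding by irreproducible discovery rate (IDR), which asks how well peaks keep their ranks between replicates. The lists give no read counts, so the depth is unknown, and the intervals given here, exact Clopper-Pearson or exact odds ratio intervals except for 1 bootstrap interval in the closing section, cover counting of genes or peaks alone. Neighbouring genes and peaks are not independent, and the p-values describe these lists rather than the spread between animals.

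The first question was how far the replicates shared their strongest regions. Of the 3897 IDR peaks, 3665 (94.0%, 95% interval 93.3 to 94.8) had a summit within 100 bp among the 3897 top regions of replicate 1, and 3253 (83.5%, 82.3 to 84.6) among those of replicate 2. Both replicates held 3083 of them (79.1%, 77.8 to 80.4) and neither held 62. IDR peaks are the top regions of the list pooled from these same replicates, so these shares describe the selected peaks and are not an independent test of agreement. The 10 strongest peaks, among them those at the ribosomal protein gene rpl-3, the eggshell gene cpg-1 and the polarity gene par-3, were in the top regions of both replicates. The share in both was 99.8% in the strongest rank quartile, 98.4% and 85.01% in the next ones, and 33.3% in the weakest. Across the 3708 peaks found in both full lists, the ranks had a Spearman rho of 0.893 and the replicate summits lay a median of 16 bp apart; peaks are not independent replicates. The share in both depends on the matching rule, from 71.9% at 50 bp to 93.1% when lists of double length were compared.

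LSL-1 peaks lay mainly just upstream of protein-coding genes. Of 3897 summits, 2269 (58.2%, 56.7 to 59.8) fell from 1000 bp upstream to 200 bp downstream of an annotated 5' end, against 21.5% of the nuclear bases, a ratio of 2.71. Among the 26103 lower-ranked pooled regions the share was 24.4% (odds ratio 4.32, 4.03 to 4.64), with p below 1e-300 in both the two-sided exact binomial test and Fisher's exact test. The median summit lay at -131 bp, and 43.7% of summits were within 500 bp upstream of the closest 5' end, against 10.8% of the lower-ranked regions. Coding exons outside promoter windows held 1.13% of summits, introns 21.7% and other intergenic sequence 15.01%, where the genome has 20.04%, 30.4% and 25.04%. In all, 2836 of 19973 protein-coding promoters (14.2%) held a summit, and 813 of the 2269 promoter peaks (35.8%) lay in windows of 2 or more genes, so the gene concerned cannot be told from position alone.

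**Figure D1:**
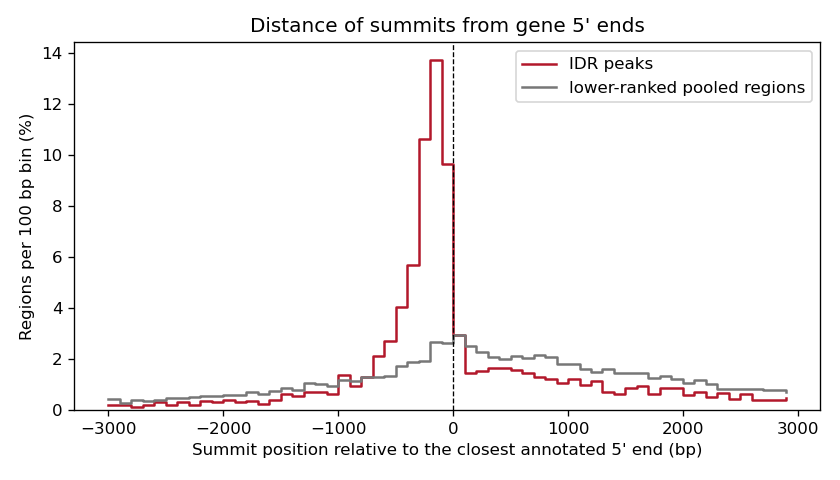
Position of summits relative to the closest annotated 5' end of a protein-coding gene (bp, horizontal axis) as the percent of regions per 100 bp bin, for IDR peaks and for the lower-ranked pooled regions. IDR peaks pile up just upstream, with 13.7% of summits in the bin that starts at -200 bp against 2.66% of the lower-ranked regions.

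The strongest peak of all lay outside every promoter window, in intergenic sequence on chromosome I from 13310491 to 13311098, 837 bp downstream of the 5' end of T04D3.8. The next ranks were at the promoters of rpl-3 (chromosome III, 3867305 to 3867932, summit at -279 bp), cpg-1 (III, 4488821 to 4489391, -244 bp) and par-3 (III, 5663454 to 5664012, -514 bp). Rank 5 was shared by Y17G9B.5 and rpl-20, rank 6 by rga-3 and K09H11.9, and rank 8 by Y55F3AR.2 and cct-8, a subunit gene of the cytosolic chaperonin. Rank 7 was at taf-12, which encodes a subunit of the general transcription factor TFIID, and rank 10 at unc-101, which encodes a clathrin adaptor subunit. Rank 9 lay in intergenic sequence upstream of the histone demethylase gene jmjd-2, with its summit at -1461 bp. The other strong peaks outside promoter windows were in an intron of pals-1 (rank 15, chromosome I, 11580068 to 11580599) and in intergenic sequence nearest to F35D11.4 (rank 21) and chdp-1 (rank 25). The genes carried by the transgene were read separately, since the transgene adds copies of them: lsl-1 had a peak of rank 845 at +71 bp that it shared with mom-4, and unc-119 had a peak of rank 3023 that was not in the top regions of both replicates.

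Genes of 4 germline lists were bound far more often than genes of 4 somatic lists. The sperm list is not among these 4 and had a low share (6 of 89, 6.74%). Of 188 genes in the lists for meiosis, germ granules and small RNAs, germline RNA regulators, and oocyte and eggshell, 131 (69.7%, 62.6 to 76.2) had a summit in the promoter window. Of 516 genes in the muscle, intestine, neuron and cuticle collagen lists, 14 did (2.71%, 1.49 to 4.51). The odds ratio was 82.4 (43.4 to 164, two-sided Fisher's exact test, p = 6.310e-79). It fell to 29.3 when both sets were limited to genes with any pooled region in the promoter window. With the window of 2000 bp upstream it was 39.2, and on autosomes alone 67.8. The lists were not matched by chromosome: muscle had 13 genes on X, intestine 28, neuron 54 and collagens 30. Of the germline lists only germ granules and small RNAs had any there (5). Nor were they matched for breadth of expression, and ribosomal protein genes, listed apart, were bound in 86.7% of cases. The contrast thus cannot separate germline genes from broadly expressed ones. Whole animals were used, so the data do not show in which cells the protein was bound.

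All 4 germline lists had a higher share of bound promoters than other protein-coding genes. In the meiosis list 39 of 54 genes (72.2%) were bound, led by the double-strand break gene dsb-2 (rank 36), the synaptonemal complex gene syp-5 (rank 38), the cohesin gene coh-4 (rank 43, shared with pid-5) and the crossover gene cosa-1 (rank 53, shared with Y71H2AM.11). Among germ granule and small RNA genes 34 of 56 (60.7%) were bound, including the Vasa-like helicase gene glh-2 (rank 111, shared with C55B7.11), tofu-6 (rank 152), znfx-1 (rank 174) and the Argonaute gene wago-4 (rank 247, shared with F58G1.2). Of the germline RNA regulators 34 of 43 (79.1%) were bound, with mex-1 at rank 17 (shared with W03C9.5), the oocyte maturation genes oma-1 at rank 34 and oma-2 at rank 56, and mog-4 at rank 67. In the oocyte and eggshell list 24 of 35 (68.6%) were bound, with egg-4 at rank 11 and egg-1 at rank 73 after cpg-1 and par-3. The odds ratios were 15.9, 9.44, 23.1 and 13.3, with Benjamini-Hochberg adjusted p over 22 lists from 3.631e-21 for meiosis to 9.635e-13 for the oocyte list (exact tests). With list genes and other genes both limited to those with any pooled region in the window, they fell to 5.22, 4.19, 9.09 and 6.39. With the closest gene alone that of germ granule genes was 4.91.

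Genes of the cell cycle and of basic cell functions were also bound more often than other genes, in all 8 of their lists. Without an untagged control analysed here, signal independent of the tagged protein was not excluded at these genes. Ribosomal protein genes had the highest share of the 22 lists, 72 of 83 (86.7%, odds ratio 40.6, 21.3 to 84.9), led by rpl-3, rpl-20, rpl-15 (rank 13, shared with K11H12.8) and rps-1 (rank 81, shared with the germline RNA regulator ifet-1). Among these 8 lists, chromosome segregation genes came next with 38 of 50 (76.0%), among them the centromere gene hcp-4 (rank 26, shared with pgk-1), the meiotic spindle kinesin gene klp-18 (rank 39, shared with cogc-2), klp-15 (rank 74, shared with ctnb-1) and the cohesin gene smc-3 (rank 130). For DNA replication and the cell cycle 33 of 45 (73.3%) were bound, with the ribonucleotide reductase gene rnr-1 at rank 27, rpa-1 at rank 66 (shared with F18A1.7), the PCNA gene pcn-1 at rank 306 and mcm-6 at rank 332 (shared with R10E11.9). Proteasome genes (22 of 33) and nuclear pore genes (18 of 27) were both bound in 66.7% of cases. The leading proteasome genes all shared their peak: rpn-2 (rank 254) with C23G10.7, pas-6 (rank 274) with CD4.11, rpn-5 (rank 351) with the cohesin gene scc-1, and rpn-9 (rank 380) with T06D8.9. Of the nuclear pore genes, npp-3 (rank 45) shared its peak with top-2, npp-20 with hxk-3 and npp-11 with ubr-1, while npp-6 had its own. Splicing genes (23 of 39, 59.0%) included rsp-6 (rank 178), prp-8 (rank 547, shared with bath-42) and the neighbours rsp-5 and snr-3, which share a peak of rank 321. Respiratory chain genes (23 of 45, 51.1%) included cox-5A (rank 32), sdhd-1 (rank 54), cox-16 (rank 69, shared with syp-2 and C24G6.8) and cox-5B. Chromatin genes (17 of 43, 39.5%, odds ratio 3.97, exact test, adjusted p = 5.335e-05) included lin-53 (rank 87, shared with nra-2), lin-9 (rank 144), rbr-2 (rank 283) and lin-54 (rank 551, shared with rpl-12). The odds ratio of ribosomal protein genes depended strongly on the setting. It was 9.15 with the closest gene alone, 16.7 among genes with any pooled region and 18.4 for the upper 50% of peaks by signal. It was 61.7 with the window of 2000 bp upstream and 69.4 with operon-like genes left out, a setting chosen after seeing the data. Among genes with any pooled region the odds ratios of the other lists fell too. They were 7.63 for chromosome segregation, 4.40 for replication, 3.902 for the proteasome, 4.79 for the nuclear pore, 2.82 for splicing and 1.93 for the respiratory chain. With the closest gene alone they were 11.3 for segregation, 10.1 for replication, 6.05 for the nuclear pore, 4.94 for splicing and 3.98 for the respiratory chain. That of the proteasome was 5.81 for the upper 50% of peaks by signal, and that of splicing rose to 15.7 with operon-like genes left out. The chromatin call was lost when list genes and other genes were both limited to those with any pooled region in the promoter window (odds ratio 1.35, exact test, adjusted p = 0.399).

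In 6 lists the share was lower than among other genes. Chemoreceptor genes had 12 bound of 1308 (0.917%, odds ratio 0.0519), with srw-90 at rank 580 and sri-5, srh-16 and str-48 sharing their peaks with other genes. Nuclear hormone receptor genes had 6 of 269 (2.23%), and the peaks of the 4 strongest, nhr-86, nhr-47, nhr-142 and nhr-15, were all shared with a neighbour. Cuticle collagen genes had 7 of 175, where the peak of col-38 (rank 535) was shared with rpl-5, and col-63, col-157 and col-71 (shared with Y49F6B.2) followed. Neuronal genes had 3 of 184 (1.63%: tdc-1, nlp-36 and nlp-4), intestinal genes 3 of 113 (2.65%: spp-28, aqp-9 and spp-26) and muscle genes 1 of 44 (2.27%), the myosin chaperone gene unc-45 at rank 2775. Of these, spp-28 shared its peak with dnj-16, tdc-1 with K01C8.2 and nlp-4 with exos-3. Adjusted p of the exact tests ran from 1.479e-69 for chemoreceptors to 0.0199 for muscle, whose call was lost with the narrower window (adjusted p = 0.0652), with the closest gene alone (0.102) and on autosomes alone (0.0575). No muscle gene was bound with replicate 2's own top list or among the upper 50% of peaks by signal. Across the settings, some chosen after seeing the data, the odds ratio ran from 0.0338 to 0.145 for chemoreceptors, 0.0877 to 0.197 for nuclear hormone receptors, 0.1005 to 0.299 for collagens, 0.0858 to 0.268 for neurons, 0.0548 to 0.357 for intestine and 0 to 0.223 for muscle.

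Another 4 lists were not called. Sperm genes had 6 bound of 89 (6.74%, odds ratio 0.436, exact test, adjusted p = 0.0538), the strongest being spe-15 (rank 574), spe-39 (rank 912, shared with spn-4), spe-44 (rank 1145, shared with smz-1) and spe-48 (rank 1500, shared with Y51F10.11). Homeobox genes had 6 of 86 (6.98%, odds ratio 0.452, exact test, adjusted p = 0.0677), including ceh-100 (shared with lips-15), ceh-92 (shared with Y66D12A.6), ceh-43 and ceh-2. Stress genes had 17 of 88 (19.3%, odds ratio 1.45, exact test, adjusted p = 0.176), led by atfs-1 (rank 171) and the mitochondrial chaperone genes hsp-60 (rank 316, shared with Y22D7AL.10) and hsp-6 (rank 345, shared with C37H5.5), then ctl-3. Histone genes had 14 of 72 (19.4%, odds ratio 1.46, exact test, adjusted p = 0.233), with his-67 and his-68 sharing a peak of rank 394 with alg-5, then his-74 (shared with ccch-3) and his-42; several histone genes are near-identical copies and are uncertain. The sperm list was called lower under 4 other settings (odds ratios from 0.325 to 0.370) and the homeobox list under 6 (from 0.240 to 0.373). Histones were called higher among genes with a pooled region (2.79, exact test, adjusted p = 0.0355). They had odds ratios below 1 for the upper 50% of peaks by signal (0.919) and with the closest gene alone (0.944).

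**Figure D2:**
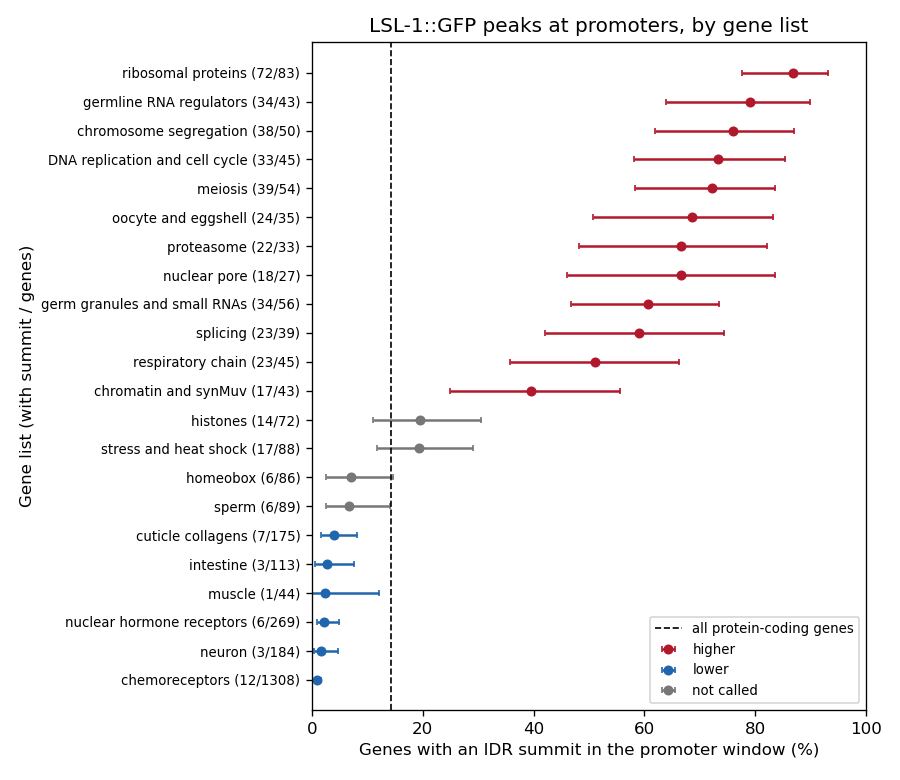
Percent of the genes of each list with an IDR summit in the promoter window (horizontal axis), with exact 95% intervals, coloured by the call after Benjamini-Hochberg adjustment; the dashed line is the 14.2% of all protein-coding genes. Ribosomal protein genes are at 86.7% and chemoreceptor genes at 0.917%.

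The X chromosome was nearly devoid of peaks. On X, 28 of 2731 protein-coding promoters (1.03%, 0.682 to 1.48) held a summit, against 2808 of 17242 on the autosomes (16.3%, 15.7 to 16.8), an odds ratio of 0.0532 (0.0352 to 0.0773; two-sided Fisher's exact test, p = 2.864e-150). X makes up 17.7% of the genome and held 61 peaks (1.57%), or 3.44 per Mb, where chromosome III had 65.4, I had 57.7, II had 49.02, IV had 39.2 and V had 30.2. The odds ratio was 0.0126 for the upper 50% of peaks by signal and 0.128 among genes with any pooled region in the window. The best peak on X ranked 1363 of 3897. Lower-ranked pooled regions were also sparser on X, at 101 per Mb against 225 to 386 on the autosomes.

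**Figure D3:**
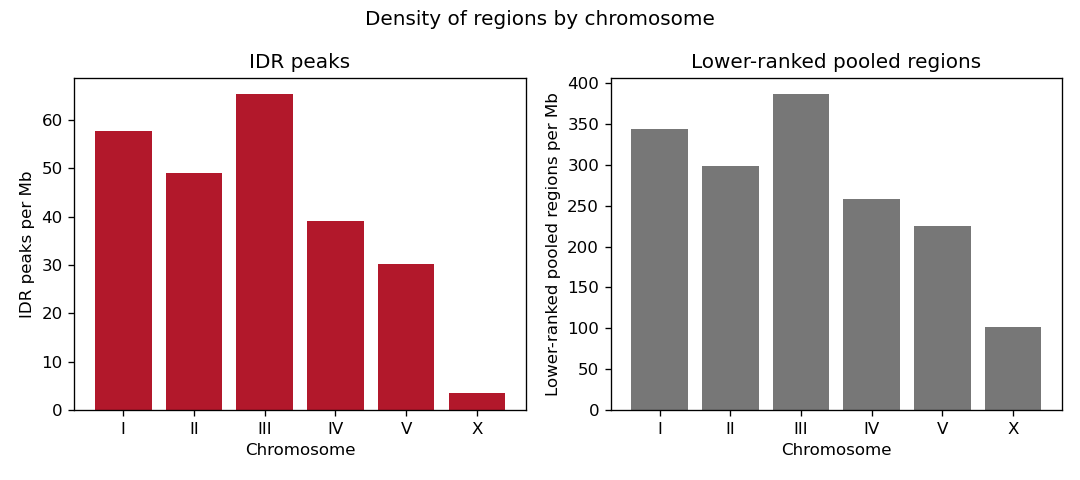
Regions per Mb on each chromosome, for IDR peaks (left) and for lower-ranked pooled regions (right). Chromosome X has 3.44 IDR peaks and 101 lower-ranked regions per Mb, the lowest bar in both panels.

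Among noncoding genes, those for tRNAs, snRNAs and snoRNAs were bound more often than protein-coding genes (14.2%). A summit lay in the window of 257 of 612 tRNA genes (41.99%, 38.0 to 46.02; odds ratio 4.37, exact test, adjusted p = 8.219e-60), 59 of 129 snRNA genes (45.7%; adjusted p = 1.671e-17) and 132 of 346 snoRNA genes (38.2%; adjusted p = 2.524e-27). Genes for piRNAs, the germline small RNAs bound by PRG-1, were bound in 136 of 15363 cases (0.885%, odds ratio 0.0540, from 0.0257 to 0.0815 over the settings). Pseudogenes (4.32%), other noncoding RNA genes (7.12%), lincRNA (7.22%), miRNA (8.43%) and antisense RNA genes (7%) were lower too, by Fisher's exact test with adjustment over 9 biotypes. The miRNA call was lost among the upper 50% of peaks by signal (odds ratio 0.661, exact test, adjusted p = 0.141), and its odds ratio moved from 0.556 to 0.347 with the narrower window. The antisense RNA call was lost with the window of 2000 bp upstream (0.641, exact test, adjusted p = 0.186) and with noncoding genes outside promoter windows alone (0.518, exact test, adjusted p = 0.137), a setting chosen after seeing the data. Without replicate 1 its odds ratio moved from 0.455 to 0.196. Among the upper 50% of peaks by signal no tRNA difference was detected (odds ratio 0.979, exact test, adjusted p = 0.943); the median rank of tRNA peaks was 2702.

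Peak strength and position went together. Promoter peaks had a mean rank of 1741 and other peaks 2239, a difference of -498 ranks (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). From the strongest to the weakest quartile the promoter share was 73.6%, 61.9%, 51.2% and 46.2%, and germline genes made up 37.7%, 21.7%, 26.6% and 18.6% of the listed genes. Peaks within 200 bp of a tRNA gene were 0.103%, 3.70%, 9.96% and 8.72% of the quartiles.

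Summits held short sequence words more often than their flanks. On chromosomes I, III and V the leading 6-base words were ACAGTA, ACTGTA, GGCGCA, CTACAG and ACGCGC, counted on both strands. On the held-out chromosomes II, IV and X, ACAGTA lay within 50 bp of 23.3% of 1495 summits and in 7.96% of flanks (ratio 2.92), ACTGTA in 23.5% and 8.03% (2.93), and CTACAG in 15.9% and 4.21% (3.74). The GC-rich words GGCGCA (18.997% and 4.01%, ratio 4.70) and ACGCGC (13.1% and 2.94%, ratio 4.42) stood above the median ratio of 1.62 for words of the same GC count; summits had 41.8% GC and flanks 35.8%. All 5 words passed the exact McNemar test, with Bonferroni-adjusted p from 6.236e-41 for GGCGCA to 1.493e-24 for ACGCGC. They are not 5 separate findings, since ACAGTA, ACTGTA and CTACAG are all parts of CTACAGTA and GGCGCA lies in the same consensus around word pairs described in the closing section. If these are copies of a repeat, sites on held-out chromosomes are not independent and the p-values are too small. The words chosen depended on the setting. ACCGTA was among the top words in 5 other settings, for example in 31.5% of the upper 50% of peaks by signal against 3.66% of flanks (ratio 8.47), and TACCGTA was among the 7-base words (14.2% and 2.61%). Longer words were CTACAGTA (14.3% and 3.08%, ratio 4.61) and AAAGGCGC (13.2% and 2.27%, ratio 5.72).

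**Figure D4:**
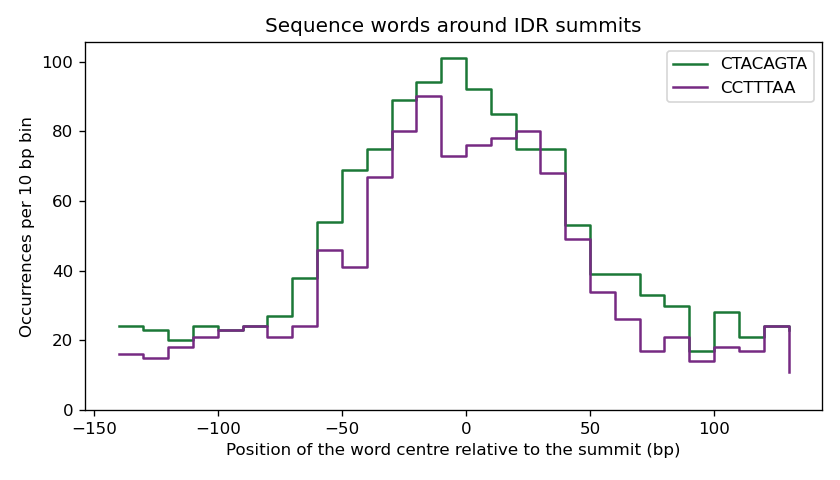
Occurrences of CTACAGTA and CCTTTAA on either strand per 10 bp bin, by distance of the word centre from the IDR summit (bp). Both words peak within 50 bp of the summit, where CTACAGTA reaches 101 occurrences in a bin and CCTTTAA reaches 90. The words were chosen for enrichment within 50 bp of summits, and the chromosomes used to choose them are included, so a central peak is largely built in.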

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

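Alternatives that left out tRNA peaks, merged close summits, left out operon-like genes or limited the noncoding genes were chosen after seeing the data. The promoter share (47.1 to 68.1%), the X odds ratio (0.0126 to 0.128), the germline against somatic odds ratio (29.3 to 96.5) and the rank difference (-549 to -441) kept their direction and their side of the threshold under every alternative run for them. All 5 words chosen under each other word setting passed, but the words differed: ACGCGC was in none of the other sets of 6-base words and ACCGTA in 5 of them, and the ratio of the leading word ran from 2.95 to 8.47. The number of lists called higher was 12 in each, and the number called lower ran from 5 to 8. The 12 were not always the same: among genes with any pooled region the chromatin list dropped out and the histone list came in. With each replicate's own top list, the promoter share was 57.3 to 57.9% and the germline odds ratio 66.7 to 82.5.

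The share of peaks in both replicates moved with its rule: 71.9% at 50 bp, 83.2% at 200 bp, 93.1% with lists of double length and 99.1% for the upper 50% of peaks by signal. A wider match or longer list can only add matches, by construction. The tRNA odds ratio fell below 1 among the upper 50% of peaks (0.979, not past the threshold) and with tRNA peaks left out (0.166), the latter by construction. A further added alternative, noncoding genes against protein-coding genes with only peaks outside protein-coding promoter windows, gave no value, because it leaves 0 bound protein-coding genes. No paired analysis was possible because there is 1 group. The unknown read depth limits how far a missing peak can be read as missing binding.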

Other observations

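Some tests were chosen after the results were seen: those of tRNA genes on X, a single coverage factor, longer flank words and chance placement. So were the gene families and peak sharing described first. Comparisons of CTACAGTA and CCTTTAA by position and rank, and of X peaks near tRNA genes, were not planned beforehand either. Both words were found in these same data. None of the 31 msp genes, which encode the major sperm proteins, had a summit in the promoter window (0%, up to 11.2% by the exact interval). Nor had any of the 6 vitellogenin genes (0%, up to 45.9%), which are too few to tell from the 14.2% of all protein-coding genes. The chromosome of these genes and the similarity of their copies were not taken into account. The core ribosomal families were bound at 41 of 47 rpl genes and 28 of 31 rps genes, and 7 of 8 mcm genes were bound. Of the 6 syp genes 5 were bound, but none of the 4 meg genes of the germ granule list, which all lie on X. Bound somatic genes shared their peak with another gene in 7 of 14 cases and bound germline genes in 66 of 131 (odds ratio 0.985, Fisher's exact test, p = 1).

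The word CTACAGTA was more frequent away from promoters. It lay within 50 bp of 23.8% of summits outside promoter windows and 10.2% inside them, with 31.0% in introns. The odds ratio was 2.75 (2.29 to 3.30, Fisher's exact test, p = 5.674e-30). If its sites are copies of a repeat, the peaks are not independent and this p-value is too small. Of the 182 peaks with a word pair, described in the last paragraph, 35.2% lay in promoter windows, against 59.4% of other peaks. The paired peaks thus feed this contrast. CCTTTAA differed less by position (17.8% outside and 14.9% inside promoter windows). It followed rank, from 29.1% of the strongest quartile to 9.23% of the weakest. On X, 37 of 61 peaks (60.7%) lay within 200 bp of a tRNA gene, against 182 of 3836 on the autosomes (4.74%, odds ratio 31.0, 17.6 to 55.2). These are shares of peaks, and X has few others: per tRNA gene the share bound was lower on X (16.7%) than on the autosomes (62.8%).

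The scarcity of peaks on X was weighed against coverage and gene content. Lower coverage or mappability of X was not excluded by the first test, since tRNA genes on X were also less often bound, 46 of 276 against 211 of 336 on the autosomes (odds ratio 0.118, 0.0788 to 0.177). A further test was added after that outcome: autosomal signals would have to be divided by 14.3 to bring promoters down to the X share but by 2.09 for tRNA genes, a ratio of 6.86 (bootstrap interval 5.47 to 8.70), which argues against 1 coverage factor as the whole cause at promoters, if the score scales with coverage. Among germline and housekeeping list genes 1 of 19 on X and 376 of 534 on the autosomes were bound (odds ratio 0.0233), so list membership alone did not account for the difference. This cannot exclude gene content, because several of the 19 are paralogs such as rpl-25.1 and asb-2. Such genes need not be like the autosomal members of their lists. Partly lower coverage may remain, and the known repression of X in the germline is a candidate explanation that was not tested.

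The peaks at tRNA genes held CTACAGTA or CCTTTAA far less often than other peaks of the same rank range. Either word lay near 4 of 197 tRNA peaks and 525 of 2176 others (odds ratio 0.0652, 0.0175 to 0.171). The words were chosen for enrichment at all IDR summits, of which 3678 of 3897 are not near a tRNA gene. A lower share at tRNA peaks was thus partly built in, and the odds ratio is not an independent test. Nearly all of these tRNA peaks lacked both words, which argues against these 2 words as what brings the protein to tRNA genes. Other words, such as ACCGTA, were not compared there. In the top regions of both replicates were 68.9% of them (62.4 to 75.01), so calls in 1 replicate alone cannot be the cause for these, but stay open for the rest, and the IDR selection itself favours peaks seen in both. Signal at highly transcribed genes that does not depend on the tagged protein may give such tRNA peaks in both replicates. Without an untagged control analysed here, this stays open. The same limit holds for peaks at other highly transcribed genes, such as those for ribosomal proteins, snRNAs and snoRNAs. No other biological explanation was tested.

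CTACAGTA was followed by CCTTTAA on the opposite strand after 4 bp in 128 pairs, where 1000 reassignments of the words between peaks never gave more than 7 in any arrangement, so chance placement is argued against. The 121 pairs with full flanks had the consensus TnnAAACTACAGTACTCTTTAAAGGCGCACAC (bases at 70% or more). Copies of a repeated element are a candidate explanation: 181 of the 182 peaks with a pair within 1 bp of that gap, a larger set than the 128 pairs, and 161 of 182 unpaired peaks shared a flanking 12-base word with another site (odds ratio 23.6), but this measure is close to its ceiling. With 20-base words and those of the sites that lie at least 1000 bp apart the counts were 86 and 12 of 172 (odds ratio 13.3, 6.73 to 28.1). Paired peaks lay in promoter windows less often than other peaks (35.2% and 59.4%), so the compared sets may also differ in position. No repeat annotation was used here, so the element is not named, and no biological explanation was tested.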
